A study of Mus musculus with 14 samples.

How the data were processed

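Satellite cells, the resident stem cells of skeletal muscle, were sorted by flow cytometry from mouse muscle as cells positive for integrin alpha 7 and CD34 and negative for CD31, CD45, CD11b and Sca1, per the labels' protocols. Their RNA was amplified and labelled with Cy3, so that each array of this single-colour Agilent design carried 1 sample. The 14 arrays fall into 5 groups by the labels: Young (3 arrays, 2 to 3 months), Old (3 arrays, 22 to 24 months) and Geriatric (2 arrays, 29 and 30 months) mice of the C57BL/6 strain, and 12-month-old SAMR1 and SAMP8 mice (3 arrays each), a senescence-resistant and a senescence-prone strain. A Geriatric sample numbered 2 was not analysed here. The labels call the samples biological replicates, so the p-values measure the spread between separate biological samples.

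The deposited scanner files hold the background-subtracted processed signal of each spot as a linear intensity, produced by Agilent Feature Extraction 10.7.3.1 per the file headers, with probe coordinates of mouse build mm9. The authors' value table holds log2 values of the same arrays. Its method is not given in the sources used here, but the deposited log2 values equalled, to within 1.17e-04, a normexp background correction with offset 50 of the mean spot signal minus its local median background, followed by quantile normalization over all spots. Every column of that table had a median of 7.80, and brighter spots had higher values on every array.

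From the scanner files, control spots and spots marked as outliers were left out, replicate spots of a probe were averaged on the log2 scale, and log2 of the processed signal was reduced by each array's 75th percentile over its 55681 probes. Levels below are therefore log2 values relative to that percentile. A probe was kept where it was well above background on at least 2 arrays of a group, which left 49927 probes. A gene was represented by its kept probe with the highest mean, which gave 32871 genes, of which 15732 carry a gene symbol, 1001 are chemosensory receptors (olfactory, vomeronasal, taste and trace amine receptors), 4488 are intergenic intervals and 11650 have other names such as clone or transcript identifiers. Genes carry the names of the array design, some of them old. Of the probes, 26300 could be matched to a current RefSeq symbol by accession, 2044 already carried a current symbol and 27337 matched neither way. Where a listed gene was not found by its name, its current symbol was tried. Among the 9220 genes with several kept probes, those with at least 1 called probe had probes of opposite sign in 63 of 246 cases for Old versus Young, 124 of 630 for Geriatric versus Young, 678 of 3007 for Geriatric versus Old and 27 of 83 for SAMP8 versus SAMR1. In the fit 524 values were missing because the spot was an outlier, and no column of per-sample values was left unmapped.

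Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, 1 coefficient per group over all 14 arrays, Benjamini-Hochberg adjusted p under 0.05). The fit shares its estimate of spread between groups, with 2.36 prior degrees of freedom and a prior variance of 0.133. The contrasts were Old versus Young, Geriatric versus Young, Geriatric versus Old, SAMP8 versus SAMR1, and the difference between the Geriatric versus Young and the SAMP8 versus SAMR1 changes. Each contrast's 23 gene lists were tested with camera, which compares a list with all other genes, at a preset correlation of 0.01, and again with a correlation estimated from the data and with fry, which asks whether a list's genes move on balance in 1 direction. List p-values were adjusted over the 23 lists of a contrast. Where a group had no array well above background for a gene, only a bound is given: the brighter group's mean against, per array of the dimmer group, the higher of the lowest signal among detected probes and the probe's own signal. Errors of log2 fold changes are standard errors (SE) from limma, with n = 3 arrays per group except n = 2 for Geriatric.

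The genes named are the 8 largest rises and 8 largest falls per contrast among genes with symbols that passed the test and whose arrays did not overlap between the groups, up to 3 members per list with the smallest p, and 12 genes fixed by name (Cdkn2a, Cdkn2b, Cdkn1a, Pax7, Myf5, Myod1, Cd34, Itga7, Ptprc, Pecam1, Itgam and Ly6a). Not all of these are printed, and some are not reported here, and a gene outside this rule is said to have been chosen after its values were seen. The comparisons, tests, filters, gene lists, this rule and most alternative settings were fixed before the data were examined.

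The arrays lie on 2 slides, each holding several groups, as read from the array identifiers in the deposited names, where no position on a slide recurs. No label gives the slide, and every value with slide as a block or within a slide rests on this reading. Slide 1 holds Young 1 and 3, Old 2, SAMR1 1 and 3 and SAMP8 2, and slide 2 the other 8 arrays, including both Geriatric arrays. Slide was fitted as a block and each contrast was repeated within each slide that holds both of its groups. Within a slide, every contrast but Geriatric versus Old has a group of 1 array, assumed to vary like the other groups. The other alternatives were 5 scalings or background corrections (normexp, quantile, percentile and median centring over probes detected on every array, and the authors' values), probe filters, other probe rules, array weights, trended and robust eBayes, a fit of the compared groups alone, the replicate number as a block, and leaving out each array. Chosen after seeing the data were fits without genes on X and Y, fits and list tests over genes with symbols only and without chemosensory receptors, and the chemosensory median of each array as a covariate.

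The scripts were tested on simulated arrays in which 200 of 32871 genes were changed. At a log2 change of 1 the test recovered 5.97% of the changed genes for Old versus Young, 5.97% for Geriatric versus Young, 0% for Geriatric versus Old and 5.97% for SAMP8 versus SAMR1. At a log2 change of 2 it recovered 62.7%, 49.3%, 62.7% and 65.7%, and at a log2 change of 3 it recovered 81.8%, 72.7%, 81.8% and 78.8%, with 8, 8, 3 and 3 false calls. A simulated list of 40 genes shifted by 0.5 was called by camera in each of these contrasts, and an unshifted list in none. The simulated genes varied independently, so this cannot show how often camera wrongly calls lists of correlated genes. Given the recovery of single genes, a gene that did not pass the test may still have changed by up to several fold. Recovery depends on how many genes change, since the Benjamini-Hochberg threshold loosens with more calls. With 6557 genes called for Geriatric versus Old, at log2 changes down to 0.51, the simulated recovery does not describe that contrast. Old versus Young (472 calls) and Geriatric versus Young (1377) also had more calls than the 200 genes changed here.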

Results

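RNA from sorted mouse satellite cells was measured on 14 single-colour arrays: 3 Young, 3 Old and 2 Geriatric C57BL/6 samples, and 3 SAMR1 and 3 SAMP8 samples. The series asks how the quiescent state of these muscle stem cells changes with age, up to geriatric age, and in a strain prone to early senescence. Between 77.2% (SAMP8 2) and 88.7% (Old 1) of probes were well above background on each array, and no spot was saturated. The median signal lay 4.61 (Old 2) to 6.66 (SAMR1 2) times above the median background. Outlier spots numbered 94 to 255 per array except on Geriatric 1, which had 969. Across genes, arrays of the same group correlated with r between 0.9447 and 0.9763 (median 0.9583 over 13 pairs) and arrays of different groups with r between 0.8473 and 0.9616 (median 0.9234 over 78 pairs). The first principal component held 46.3% of the variance and the second 10.6%. The first lay between −189.81 and −52.24 on Young and Old arrays and between 34.61 and 110.69 on Geriatric, SAMR1 and SAMP8 arrays, so the Geriatric comparisons with Young and Old cells cross this division. Geriatric 3 correlated with SAMR1 arrays with r between 0.9546 and 0.9559 and with Young arrays with r between 0.9152 and 0.937, whereas for Geriatric 1 these ranges overlapped (0.9366 to 0.9405 and 0.9202 to 0.9372). The small number of arrays limits the precision of every value below.

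Sex-linked transcripts divided the arrays in the same way as the first component, although the labels call all mice male. Xist, the RNA that silences 1 X chromosome in female cells, had a level of 5.69 ± 0.15 (SD, n = 3) in Young and 5.26 ± 0.26 (SD, n = 3) in Old samples, on the log2 scale relative to each array's 75th percentile. On the Geriatric arrays Xist was not well above background, and in SAMR1 it was so on 1 of 3 arrays. It was above background on 3 of 3 SAMP8 arrays, at a mean level of −4.14. Ddx3y, Uty and Kdm5d, genes of the Y chromosome, were not well above background on any Young or Old array and were well above it on every Geriatric, SAMR1 and SAMP8 array. By these transcripts the Young and Old samples read as female, against their labels, and the Geriatric samples as male. Geriatric samples thus differed from Young and Old samples in their sex-linked transcripts as well as in age, and the 2 differences are confounded. Old versus Young and SAMP8 versus SAMR1 compared samples alike in Ddx3y, Uty and Kdm5d detection.

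**Figure D1:**
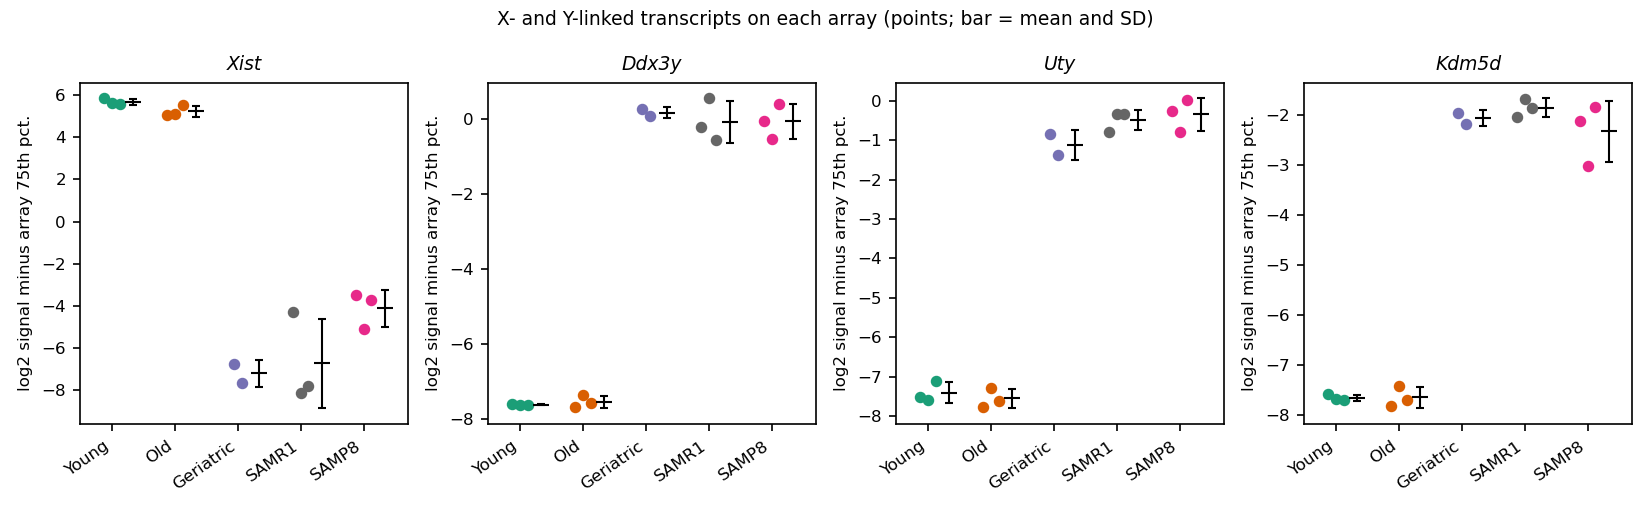
Levels of Xist, Ddx3y, Uty and Kdm5d (log2 relative to the array's 75th percentile) on each array, with the mean and SD of each group. Young and Old samples lay high in Xist (means 5.69 and 5.26) and low in the Y-linked genes, and the Geriatric, SAMR1 and SAMP8 samples the other way round.

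Genes that define the sort did not pass the test in any of the 4 comparisons, which does not show that the sorted cells were alike. Over the 4 comparisons the lowest adjusted p was 0.249 for Itga7 and 0.252 for Cd34, the antigens the cells were selected on, and 0.839 for Ptprc, 0.433 for Pecam1, 0.136 for Itgam and 0.598 for Ly6a, which mark the cells sorted away. Of these, Itgam read between 7.42 and 8.70 on the 14 arrays. Pecam1 read between 2.39 and 3.80 on the SAMR1 arrays and SAMP8 1 and 2, 0.61 on SAMP8 3, and between −4.95 and 0.11 on Young, Old and Geriatric arrays. Ly6a had mean levels of −0.44 in SAMR1 and −0.11 in SAMP8 samples and of −3.62, −2.87 and −2.67 in Young, Old and Geriatric samples.

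Old cells expressed more Pdgfrb, a growth factor receptor of perivascular and mesenchymal cells (log2 change 2.44 ± 0.32 (SE), n = 3 against 3, adjusted p = 0.00609), and less Plac9, a small secreted protein (−4.11 ± 0.24, adjusted p = 1.89e-05), than Young cells. Fn1, which encodes fibronectin, a component of the satellite cell niche, fell by 1.71 ± 0.30 (adjusted p = 0.0219). Dkk2, a secreted Wnt inhibitor that was not well above background in Old cells, was at least 1.86-fold lower (adjusted p = 0.00701). Immediate early and stress genes and Polycomb group genes were lower as lists with camera's preset correlation, but not with an estimated one (adjusted p = 0.772 for both). In all, 472 genes differed (393 higher, 79 lower), of which 198 had gene symbols (141 higher, 57 lower) and 33 were chemosensory receptors, all higher in Old cells. The higher share fell from 83.3% to 67.8% under quantile normalization.

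Rises with a symbol included those of Vmn1r86, a vomeronasal receptor (at least 8.22-fold, adjusted p = 0.000951), and Prss21, a serine protease of the testis (at least 7.85-fold, adjusted p = 0.00213). Among others were those of Uroc1, an enzyme of histidine breakdown (4.72 ± 0.80, adjusted p = 0.0207, measured on 2 of 3 Young arrays), and Btla, an inhibitory receptor of lymphocytes (4.61 ± 0.83, adjusted p = 0.0246). Falls beside that of Plac9 included Sox11, a transcription factor of developing tissue (−2.89 ± 0.53, adjusted p = 0.0262), and Abcc9, a subunit of potassium channels in muscle and perivascular cells (−2.70 ± 0.41, adjusted p = 0.0123). The histone gene Hist1h2bg (−2.02 ± 0.38, adjusted p = 0.0304) and the zinc finger gene Zfp82 (−1.99 ± 0.31, adjusted p = 0.0148) fell too. For every gene said in this text to have risen or fallen, all arrays of 1 group lay above all arrays of the other, which chance gives for 10% of genes with 3 arrays against 3 and 20% with 2 against 3.

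Among 33 measured immediate early and cell isolation stress genes, 1 fell over all genes (0 rose), and 11 fell and 1 rose adjusted over the list alone. The member that fell over all genes was Dusp6, a phosphatase that restrains ERK signalling (−1.18 ± 0.22, adjusted p = 0.0269). The heat shock genes Hspa1a (−1.01, adjusted p = 0.0649) and Dnajb1 (−1.14, adjusted p = 0.0735) did not pass over all genes. The list's mean shift was −0.28 (camera adjusted p = 4.81e-06, adjusted p = 0.772 with an estimated correlation). It was −0.33 with slide as a block and −0.27 and −0.47 within slides 1 and 2. Of 28 Polycomb genes, which keep target genes silent through histone modification, 1 fell, Pcgf6 (−1.19 ± 0.26, adjusted p = 0.048), and 2 fell adjusted over the list alone. Their mean shift was −0.29 (camera adjusted p = 0.000475, 0.772 as adjusted p with an estimated correlation), −0.36 with slide as a block and −0.36 and −0.42 within the slides. Without Young 2 the adjusted p was 0.0563. These 2 lists were also called when tested against genes with symbols only (adjusted p = 0.0011 and 0.0186).

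Lower as lists only against all genes, intergenic and receptor probes included, were 4 more, each with an adjusted p of 0.772 with an estimated correlation. In satellite cell identity and quiescence (camera adjusted p = 0.0116, and 0.134 against genes with symbols) 1 of 30 genes rose and 0 fell, adjusted over the list alone too. In the Notch pathway (0.0128, and 0.134) 1 of 21 rose and 0 fell, and 1 each adjusted over the list alone. In oxidative phosphorylation (0.0014, and 0.093) 1 of 75 rose and 0 fell, also adjusted over the list alone. Of 40 autophagy and lysosome genes (0.0464, and 0.379) 0 changed, and 1 fell adjusted over the list alone. The members that rose were Foxo3, a transcription factor that preserves quiescence (0.91 ± 0.20, adjusted p = 0.0494), Maml2, a Notch coactivator (0.82 ± 0.18, adjusted p = 0.0477), and Cox6b1, a subunit of cytochrome c oxidase (0.97 ± 0.20, adjusted p = 0.0417), against the direction of their lists. As the mean of its probes, Foxo3 changed by only 0.02 (adjusted p = 0.979). The Notch target Hey1 had a log2 change of −1.08 (adjusted p = 0.054). Within slide 2 the mean shift of oxidative phosphorylation turned to 0.11, from −0.14, and the other lists named kept their direction within both slides. Tested against genes with symbols, the senescence-associated secretory phenotype (adjusted p = 0.025), interferon response and antigen presentation (0.00561) and leukocyte markers (0.0193) were higher, although they did not pass against all genes, or with an estimated correlation (adjusted p = 0.772 for each).

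Other lists did not pass between Old and Young cells. Myogenic activation and differentiation genes had an adjusted p of 0.502 (0 of 24 changed, 1 fell adjusted over the list alone). Cell cycle inhibitors and senescence genes had 0.27 (0 of 33, 2 fell adjusted over the list alone) and the secretory phenotype 0.255 (1 of 42 rose, 2 rose and 1 fell adjusted over the list alone). In the last, Il15, a cytokine of muscle, was at least 1.07-fold higher (adjusted p = 0.0276, measured on 1 of 3 Old arrays). Il6 had a log2 change of 1.68 (adjusted p = 0.0546, measured on 2 of 3 Young arrays). The adjusted p was 0.376 for cell cycle and DNA replication, 0.0702 for interferon response, 0.0772 for extracellular matrix (Fn1 fell), and 0.0598 for TGF-beta and BMP signalling. It was 0.408 for the Wnt pathway (Dkk2 fell), 0.904 for ribosomal proteins and 0.734 for oxidative stress and glutathione, in which Gstm2 rose (1.12 ± 0.22, adjusted p = 0.0351). Of the marker lists for other cells, it was 0.488 for endothelial cells, 0.119 for leukocytes, and 0.396 for mesenchymal cells. It was 0.649 for muscle fibres, 0.649 for smooth muscle and pericytes (Pdgfrb rose, Abcc9 fell), 0.376 for Schwann cells and 0.441 for red cells. For 6 of the 23 lists the median, mean and test differed in sign, namely myogenic, cell cycle inhibitors, ribosomal, oxidative stress, mesenchymal and smooth muscle.

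The senescence and lineage genes fixed by name did not pass between Old and Young cells. Cdkn2a, which encodes the cell cycle inhibitor p16 and p19, had a log2 change of 0.70 ± 0.22 (adjusted p = 0.135), Cdkn2b of 0.03 (adjusted p = 0.978) and Cdkn1a of 0.51 (adjusted p = 0.68). Those of the lineage genes were, for the satellite cell regulator Pax7 −0.69 ± 0.21 (adjusted p = 0.128), Myf5 −1.05 (adjusted p = 0.198) and Myod1 −0.04 (adjusted p = 0.937). B2m (0.88, adjusted p = 0.0649) and C1qb (1.11, adjusted p = 0.0546) did not pass either.

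The count of 472 genes was 729 with slide as a block. Slide 1 holds 1 Old array and slide 2 holds 1 Young array, so fits within a slide (2 and 3 residual degrees of freedom) say little about the calls. In them limma called 0 genes on slide 1 (4901 at an unadjusted p under 0.05, lowest adjusted p = 0.101) and 0 on slide 2 (2723, lowest adjusted p = 0.119). All 26 passing genes named in this text kept their direction in both. The calls of Foxo3, Maml2, Pcgf6 and Cox6b1 were lost in 21, 21, 20 and 15 of 29 other settings, that of Foxo3 without any 1 of the 14 arrays. The count rested on single arrays: 85 genes without Old 1, 143 without Young 1, 294 without Old 2, 312 without Young 2, 277 without SAMR1 1, 313 without SAMR1 2 and 793 without Old 3.

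Single genes that Geriatric cells expressed more than Young cells included secreted factors, although the secretory phenotype as a list did not pass (camera adjusted p = 0.148). Ccl11, an eosinophil-attracting chemokine, rose by 5.42 ± 0.57 on the log2 scale (SE, n = 2 against 3, adjusted p = 0.000589, measured on 2 of 3 Young arrays), and Hgf, the growth factor that activates satellite cells, by 3.97 ± 0.68 (adjusted p = 0.00821). Serpine2, a secreted protease inhibitor, rose by 2.93 ± 0.26 (adjusted p = 0.000216), and the insulin-like growth factor binding proteins Igfbp5 and Igfbp7 by 2.69 ± 0.49 (adjusted p = 0.0113) and 2.04 ± 0.41 (adjusted p = 0.0191). Mean levels of Ccl11, Hgf, Serpine2, Igfbp5 and Igfbp7 were −1.81, −0.424, 0.407, 4.35 and 2.215 in SAMR1 cells. They were −4.8, −4.575, −1.873, 2.113 and −0.893 in Young and 0.61, −0.61, 1.054, 4.798 and 1.145 in Geriatric cells. The SAMR1 levels lay nearer to the Geriatric ones, and Geriatric samples also differed from Young ones in sex-linked transcripts. These rises therefore cannot be assigned to age alone. Cdkn2a rose by 1.0 ± 0.24 (adjusted p = 0.0427), a call lost in 18 of 28 settings. Interferon and Polycomb genes were higher as lists with the preset correlation, but not with an estimated one (adjusted p = 0.443 and 0.483), and Polycomb genes did not pass with slide as a block (adjusted p = 0.0505). In all, 1377 genes differed (519 higher, 858 lower), of which 535 had symbols (357 higher, 178 lower) and 137 were chemosensory receptors (1 higher, 136 lower). Of all calls 37.7% were higher, against 49.7% with the authors' values.

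Sex-linked genes were among the changes: Ddx3y was at least 48.4-fold higher in Geriatric cells (adjusted p = 7.65e-07), Uty at least 19.7-fold and Kdm5d at least 10.2-fold, and Xist at least 3130-fold lower (adjusted p = 6.42e-05). Spock3, a matrix proteoglycan (at least 8.02-fold, adjusted p = 7.79e-06), Grhl1, an epithelial transcription factor (at least 10.5-fold, adjusted p = 0.000328), and Cyp4f15, a cytochrome P450 (at least 23-fold, adjusted p = 0.00654), also rose. The vomeronasal receptors Vmn1r121 (at least 138-fold lower, adjusted p = 0.00326), Vmn1r101 (at least 111-fold) and Vmn1r104 (at least 92.2-fold) fell, as did Hrnr, a gene of the cornified skin layer (at least 76.5-fold, adjusted p = 0.0194). Vomeronasal receptors are close copies of each other, so the values of single members are uncertain.

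Of 41 interferon response and antigen presentation genes, 5 rose and 0 fell, and 6 rose adjusted over the list alone. They included Ifit3 (2.76 ± 0.62, adjusted p = 0.0322) and Ifih1 (1.38, adjusted p = 0.0316), which act against viral RNA, and the immunoproteasome subunit Psmb8 (1.62 ± 0.30, adjusted p = 0.0128). Their mean shift was 0.50 (camera adjusted p = 9.73e-07, adjusted p = 0.443 with an estimated correlation), 0.52 with slide as a block and 0.31 within slide 2. Among 28 Polycomb genes 3 rose and 0 fell, and 5 rose adjusted over the list alone. The 3 were Cbx7 (1.35 ± 0.26, adjusted p = 0.0146), a subunit of the complex that represses Cdkn2a, Eed (1.08, adjusted p = 0.0325) and Phf1 (1.02, adjusted p = 0.0398). Leaving out 1 array ended the calls of Cbx7, Eed and Phf1 in 2, 5 and 9 of 14 cases. The mean shift of the Polycomb genes was 0.29 (camera adjusted p = 0.00131, adjusted p = 0.483 with an estimated correlation). With slide as a block it was 0.16 (adjusted p = 0.0505) and within slide 2 it was 0.07. Both lists were called against genes with symbols only (adjusted p = 0.000172 and 0.022). Mean levels of the Polycomb list were −0.849 to −0.5 on Young, −0.442 and −0.413 on Geriatric and −0.518 to −0.428 on SAMR1 arrays. Those of the interferon list were −0.855 to −0.372, 0.086 and −0.217, and −0.056 to 0.144. List shifts between Geriatric and Young cells cross the division in sex-linked transcripts and cannot be assigned to age alone.

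Immediate early and stress genes were lower (mean shift −0.42, camera adjusted p = 0.0386, adjusted p = 0.637 with an estimated correlation; −0.52 with slide as a block, −0.66 within slide 2). Of 33 genes 2 fell, and 3 adjusted over the list alone. Nr4a2, an orphan nuclear receptor, fell by 1.85 ± 0.23 (adjusted p = 0.00166) and Dusp6 by 1.32 ± 0.24 (adjusted p = 0.0125). The list was not called without Geriatric 3 (adjusted p = 0.184) or Young 2 (adjusted p = 0.331). Cytosolic ribosomal protein genes had a mean shift of −0.31 (camera adjusted p = 0.000314, adjusted p = 0.637 with an estimated correlation; −0.23 with slide as a block and −0.06 within slide 2), which flipped to 0.07 under quantile normalization and 0.06 in the authors' values. Relative to the mean of all other genes it was −0.075, and 0.13 within slide 2. None of the 76 passed, over all genes or adjusted over the list alone, and without Young 1 the list's adjusted p was 0.083. Against genes with symbols only these 2 lists were lower (adjusted p = 0.00219 and 1.1e-07), and so were myogenic genes (adjusted p = 0.022), cell cycle and DNA replication (0.00815) and leukocyte markers (0.00815). The last 3 did not pass against all genes with an estimated correlation (adjusted p = 0.637, 0.664 and 0.637).

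Called only against all genes, and higher in Geriatric cells, were 6 further lists. Of 21 Notch genes (camera adjusted p = 0.0222, adjusted p = 0.601 with an estimated correlation and 0.128 against genes with symbols), 2 rose, the target Hes1 (1.64 ± 0.24, adjusted p = 0.00373) and the ligand Jag1 (2.07 ± 0.45, adjusted p = 0.0275). Adjusted over the list alone 5 Notch genes rose and 1 fell. Extracellular matrix genes (0.0331, 0.637 as adjusted p with an estimated correlation, 0.3 against symbols) included 5 of 39 that rose, 7 adjusted over the list alone, such as the basement membrane nidogens Nid1 (2.23 ± 0.29, adjusted p = 0.00186) and Nid2 (2.17 ± 0.40, adjusted p = 0.012). TGF-beta and BMP genes (0.0222, 0.615 as adjusted p with an estimated correlation, 0.233 against symbols) included 3 of 41 that rose, and 6 up and 3 down adjusted over the list alone. The 3 were the receptors Tgfbr2 (1.29 ± 0.26, adjusted p = 0.0178) and Acvr2a (1.05, adjusted p = 0.0431) and the BMP target Id1 (0.92, adjusted p = 0.0316). In the Wnt pathway (0.0386, 0.443 as adjusted p with an estimated correlation, 0.324 against symbols), 2 of 38 rose and 1 fell, and 3 rose and 1 fell adjusted over the list alone. They were Sfrp2, a secreted modulator (4.57 ± 0.62, adjusted p = 0.00249, measured on 2 of 3 Young arrays), the receptor Fzd4 (1.16, adjusted p = 0.0252), and Dkk2 (at least 2.6-fold lower, adjusted p = 0.00175). Glutathione and oxidative stress genes (0.00639, 0.443 as adjusted p with an estimated correlation, 0.093 against symbols) had 4 of 37 up, also adjusted over the list alone. Among them were the glutathione transferases Gsta4 (2.28, adjusted p = 0.00266), Gstt3 (1.85, adjusted p = 0.00204) and Gstm2 (1.54, adjusted p = 0.00605). Autophagy and lysosome genes (0.00553, 0.583 as adjusted p with an estimated correlation, 0.093 against symbols) had 0 of 40 past the test either way. With slide as a block 4 lists were called and Notch, Polycomb, autophagy, matrix, TGF-beta and Wnt genes were not (adjusted p = 0.127, 0.0505, 0.156, 0.159, 0.159 and 0.0559). Within slide 2 the mean shifts of Notch (−0.08), autophagy (−0.01) and TGF-beta genes (−0.08) turned.

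The cell cycle inhibitor and senescence list did not pass (adjusted p = 0.252), although 4 of its 33 genes rose, and 5 rose and 4 fell adjusted over the list alone. Perp, a p53 target, rose by 2.63 ± 0.33 (adjusted p = 0.00168). Neither did the secretory phenotype (adjusted p = 0.148; 4 of 42 rose, and 5 rose and 3 fell adjusted over the list alone), in which Il15 was at least 1.69-fold higher (adjusted p = 0.00612). The adjusted p was 0.383 for satellite cell identity, 0.148 for myogenic genes, 0.0748 for oxidative phosphorylation and 0.0893 for cell cycle and DNA replication, with the proliferation marker Mki67 at −1.28 (adjusted p = 0.0529). For other cell types it was 0.367 for endothelial cells, 0.48 for muscle fibres, 0.43 for Schwann cells and 0.252 for red cells. It was 0.0748 for leukocytes, where Nkg7 of cytotoxic lymphocytes fell (−1.08, adjusted p = 0.0453). It was 0.178 for mesenchymal cells, where Dpt rose (1.48, adjusted p = 0.0205) and Thy1 fell (−3.04 ± 0.55, adjusted p = 0.011). For smooth muscle and pericytes it was 0.347, and Pdgfrb rose (2.66 ± 0.35, adjusted p = 0.00224) and Abcc9 fell (−2.94 ± 0.45, adjusted p = 0.00497). Median, mean and test differed in sign for 5 lists, satellite cell, endothelial, mesenchymal, muscle fibre and Schwann cell genes.

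The probe for Cdkn2a lies on chromosome 4 at 88920405 to 88920464 (mm9), and without exon annotation it is not known here which of the p16 and p19 transcripts it measures. Its mean level was −4.10 in Young, −3.40 in Old and −3.10 in Geriatric cells. The call in Geriatric cells lay near the threshold: leaving out any 1 of 11 arrays gave an adjusted p between 0.0506 and 0.229, with the log2 change between 0.82 and 1.18. The adjusted p was 0.0994 with the authors' values (range over all settings 0.0175 to 0.494), and the call was lost in 18 of 28 settings. Over all settings the log2 change ran from 0.37, after normexp correction, to 1.24. Cdkn2b (−0.85, adjusted p = 0.147), Cdkn1a (−1.22, adjusted p = 0.237), Pax7 (−0.12, adjusted p = 0.788), Myf5 (1.29, adjusted p = 0.121) and Myod1 (−0.36, adjusted p = 0.279) did not pass.

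**Figure D2:**
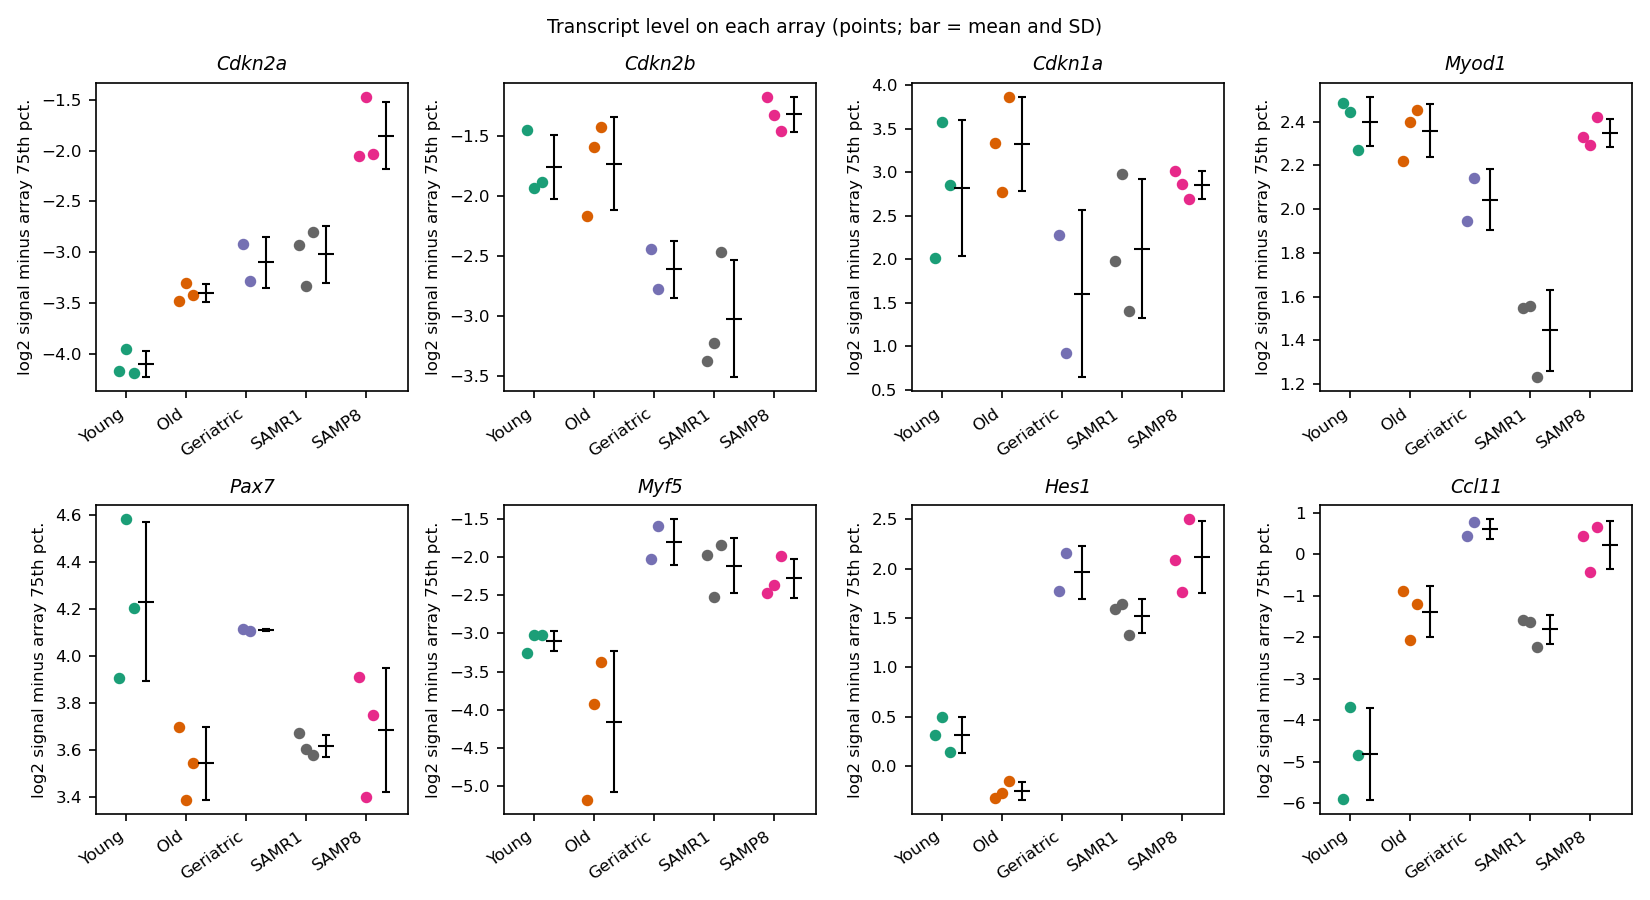
Levels of Cdkn2a, Cdkn2b, Cdkn1a, Myod1, Pax7, Myf5, Hes1 and Ccl11 (log2 relative to the array's 75th percentile) on each array, with the mean and SD of each group. Cdkn2a had means of −4.10 in Young, −3.40 in Old, −3.10 in Geriatric, −3.02 in SAMR1 and −1.85 in SAMP8 samples.

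The 1377 calls fell to 862 with slide as a block. Within slide 2, which holds 1 Young array and leaves 3 residual degrees of freedom, limma called 2 genes (3055 at an unadjusted p under 0.05), too small a fit to weigh the calls. All 51 passing genes named in this text kept their direction there. Single arrays also moved the count, to 416 without Geriatric 3, 600 without Geriatric 1 and 654 without Young 3.

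Geriatric and Old cells differed at more genes than the other pairs. Hes1, a Notch target that maintains quiescence, rose by 2.21 ± 0.24 (log2, SE, n = 2 against 3, adjusted p = 0.000291), its relative Hey1 by 1.67 ± 0.27 (adjusted p = 0.0021) and Myf5, a marker of committed satellite cells, by 2.34 ± 0.43 (adjusted p = 0.00431). Cdk1, which drives mitosis (−1.42, adjusted p = 0.00515), Mki67 (−1.55, adjusted p = 0.00875) and Ccne1, a cyclin of the S phase entry (−1.51, adjusted p = 0.0124), fell. Mean levels of Hes1, Hey1 and Myf5 were 1.52, 3.18 and −2.12 in SAMR1 cells. They were 1.96, 2.24 and −1.81 in Geriatric and −0.25, 0.57 and −4.15 in Old cells. For Cdk1, Mki67 and Ccne1 too, SAMR1 levels lay nearer to the Geriatric than to the Old ones. These changes cannot be assigned to age alone. Polycomb genes were higher and leukocyte markers lower as lists with the preset correlation, but not with an estimated one (adjusted p = 0.414 and 0.583). Of 6557 genes that differed (1815 higher, 4742 lower), 2617 had symbols (1339 higher, 1278 lower) and 498 were chemosensory receptors (1 higher, 497 lower). Of all calls 27.7% were higher, against 47.0% under quantile normalization and 42.9% with the authors' values. The median change over all genes was −0.224 here and 0.028 under quantile normalization. In the other comparisons it was 0.061 and −0.045 (Old versus Young), −0.179 and −0.041 (Geriatric versus Young) and 0.008 and −0.005 (SAMP8 versus SAMR1).

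Ddx3y (at least 49.1-fold, adjusted p = 8.52e-07), Uty (at least 20-fold) and Kdm5d (at least 10.3-fold) were again higher and Xist lower (at least 2320-fold, adjusted p = 3.36e-05). Beyond the sex-linked genes, Lgals3, a lectin of macrophages and regenerating muscle (at least 14.5-fold, adjusted p = 0.00373), Pid1, an adaptor in insulin signalling (at least 4.92-fold, adjusted p = 2.25e-05), and Lamc3, a laminin chain (4.17 ± 0.43, adjusted p = 0.000208), rose. Hrnr (at least 195-fold lower), Vmn1r121 (at least 198-fold), the urinary protein gene Mup20 (at least 47.3-fold, adjusted p = 0.00194) and the olfactory receptor Olfr119 (at least 35.6-fold, adjusted p = 4.66e-05) fell.

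Of 28 Polycomb genes 8 rose and 0 fell, and 10 rose adjusted over the list alone, including Phf1 (1.45, adjusted p = 0.00259), Cbx7 (1.21, adjusted p = 0.00911) and Eed (1.13, adjusted p = 0.00947). Their mean shift was 0.58 (camera adjusted p = 1.15e-06, adjusted p = 0.414 with an estimated correlation), 0.52 with slide as a block and 0.50 within slide 2. The mean level of these genes was −0.442 and −0.413 on Geriatric, −0.518 to −0.428 on SAMR1 and −1.177 to −0.896 on Old arrays. SAMR1 levels thus lay nearer to the Geriatric ones. Every list shift between Geriatric and Old cells crosses the division in sex-linked transcripts and cannot be assigned to age alone. Among 24 leukocyte markers 5 fell, and 8 adjusted over the list alone, such as the monocyte receptor Cd14 (−1.44, adjusted p = 0.00273), lysozyme Lyz2 (−1.70, adjusted p = 0.0251) and Nkg7 (−1.06, adjusted p = 0.019). The shift of this list was −1.27 (camera adjusted p = 0.00986, adjusted p = 0.583 with an estimated correlation; −1.18 with slide as a block, −1.25 within slide 2), and it was not called without Geriatric 3 (adjusted p = 0.0828). Ribosomal protein genes had a mean shift of −0.36, flipped to 0.04 under quantile normalization and in the authors' values (camera adjusted p = 0.00169, adjusted p = 0.717 with an estimated correlation; −0.32 with slide as a block, −0.30 within slide 2). On average these genes fell less than the others, by a difference in means of 0.08, and 0.14 within slide 2. Of 76 measured, 3 fell and 0 rose, with Rpl28 at −0.93 (adjusted p = 0.0209) and Rpl7a at −0.71 (adjusted p = 0.0298) among those that fell, and 0 passed adjusted over the list alone. As the mean of its probes Rpl7a changed by −0.01 (adjusted p = 0.977). These 3 lists were called against genes with symbols only (adjusted p = 0.000224, 0.000137 and 1.82e-07 for Polycomb, leukocyte and ribosomal genes).

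The other 9 lists called against all genes were higher in Geriatric than in Old cells and were not called against genes with symbols. Notch genes (camera adjusted p = 0.00169, adjusted p = 0.456 with an estimated correlation and 0.0652 against symbols) had 6 of 21 up, the same adjusted over the list alone, with Jag1 up by 2.29 ± 0.45 (adjusted p = 0.00625). In the satellite cell list (0.0228, 0.694 as adjusted p with an estimated correlation, 0.341 against symbols) 2 of 30 rose and 1 fell, also adjusted over the list alone. The rises were Myf5 and Spry1, a brake on growth factor signalling in quiescent satellite cells (1.68 ± 0.36, adjusted p = 0.00944), and the fall Foxo3 (−1.29 ± 0.22, adjusted p = 0.0029, but −0.31 as the mean of its probes, adjusted p = 0.419). Matrix genes (0.00169, 0.583 as adjusted p with an estimated correlation, 0.137 against symbols) had 8 of 39 up, over all genes and adjusted over the list alone, Nid1 among them (1.60, adjusted p = 0.00383). TGF-beta genes (0.00169, 0.456 as adjusted p with an estimated correlation, 0.137 against symbols) had 6 of 41 up and 1 down in both counts, including Tgfbr2 (1.39, adjusted p = 0.00441) and Id1 (0.98, adjusted p = 0.00835). For oxidative phosphorylation (0.00102, 0.717 as adjusted p with an estimated correlation, 0.137 against symbols) 2 of 75 rose and 1 fell in both counts. The rises were Sdha of complex II (1.01, adjusted p = 0.0155) and Ndufs1 of complex I (0.87, adjusted p = 0.0177) and the fall Cox6b1 (−1.04, adjusted p = 0.00918). Autophagy genes (0.000592, 0.456 as adjusted p with an estimated correlation, 0.0652 against symbols) had 3 of 40 up, and 1 adjusted over the list alone, with Atg13 (0.99, adjusted p = 0.00874) and Bnip3 (1.19, adjusted p = 0.0246). Interferon genes (0.00994, 0.583 as adjusted p with an estimated correlation, 0.341 against symbols) had 4 of 41 up and 1 down in both counts, with Tap2 (1.41, adjusted p = 0.00921) and Psmb8 (1.13, adjusted p = 0.0245). Their mean shift was 0 within slide 2. The Wnt pathway (0.0309, 0.414 as adjusted p with an estimated correlation, 0.466 against symbols) had 3 of 38 up in both counts, with Sfrp2 (3.72, adjusted p = 0.00259). Oxidative stress genes (0.00986, 0.456 as adjusted p with an estimated correlation, 0.306 against symbols) had 4 of 37 up and 1 down in both, with Gsta4 (1.54, adjusted p = 0.00756).

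Lists that did not pass held single genes that changed. Cell cycle inhibitors (adjusted p = 0.0847; 5 of 33 rose and 2 fell, 7 and 6 adjusted over the list alone) included Perp (2.61, adjusted p = 0.000562) and Cdkn2c (2.16, adjusted p = 0.0205), which rose, and the stress gene Sesn2 (−1.27, adjusted p = 0.0171), which fell. The secretory phenotype (adjusted p = 0.665; 3 of 42 rose and 6 fell, also adjusted over the list alone) included Serpine2 (2.20, adjusted p = 0.000393) and Hgf (3.13, adjusted p = 0.00958, measured on 2 of 3 Old arrays), which rose, and the macrophage elastase Mmp12 (at least 8.4-fold lower, adjusted p = 0.00897). Immediate early genes (adjusted p = 0.258; 2 rose, 3 fell) went both ways, Fos rising by 1.3 (adjusted p = 0.00228) and Nr4a2 and Fosl1 falling by 1.43 and 3.48 (adjusted p = 0.00225 and 0.00564). Cell cycle and DNA replication had an adjusted p of 0.572 (3 of 36 fell, in both counts) and myogenic genes 0.509. Tnnc1, a troponin of slow muscle, fell by 0.90 (adjusted p = 0.0313). For other cells the adjusted p was 0.959 for endothelial and 0.126 for mesenchymal (Dpt rose by 1.05, adjusted p = 0.0325, and Thy1 fell by 2.26, adjusted p = 0.0157). It was 0.913 for muscle fibre (Mylpf at least 2.45-fold lower, adjusted p = 0.02), 0.661 for smooth muscle (Cnn1 fell by 1.05, adjusted p = 0.0184), 0.272 for Schwann and 0.78 for red cell genes (Ermap fell by 1.10, adjusted p = 0.00407). Signs of median, mean and test differed for 6 lists, the secretory phenotype, immediate early, endothelial, mesenchymal, muscle fibre and Schwann cell genes. Cdkn2a (0.30 ± 0.24, adjusted p = 0.395), Cdkn2b (−0.88, adjusted p = 0.0683), Cdkn1a (−1.72, adjusted p = 0.0528), Pax7 (0.57, adjusted p = 0.105) and Myod1 (−0.31, adjusted p = 0.242) did not pass.

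With slide as a block 7095 genes differed, and within slide 2, which holds both Geriatric and 2 Old arrays, limma called 1554 (134 higher, 1420 lower). All 57 passing genes named in this text kept their direction there and 18 passed. The count was 1995 without Geriatric 3, 3564 without Geriatric 1, 3860 without Old 1 and 4204 without Old 2.

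**Figure D3:**
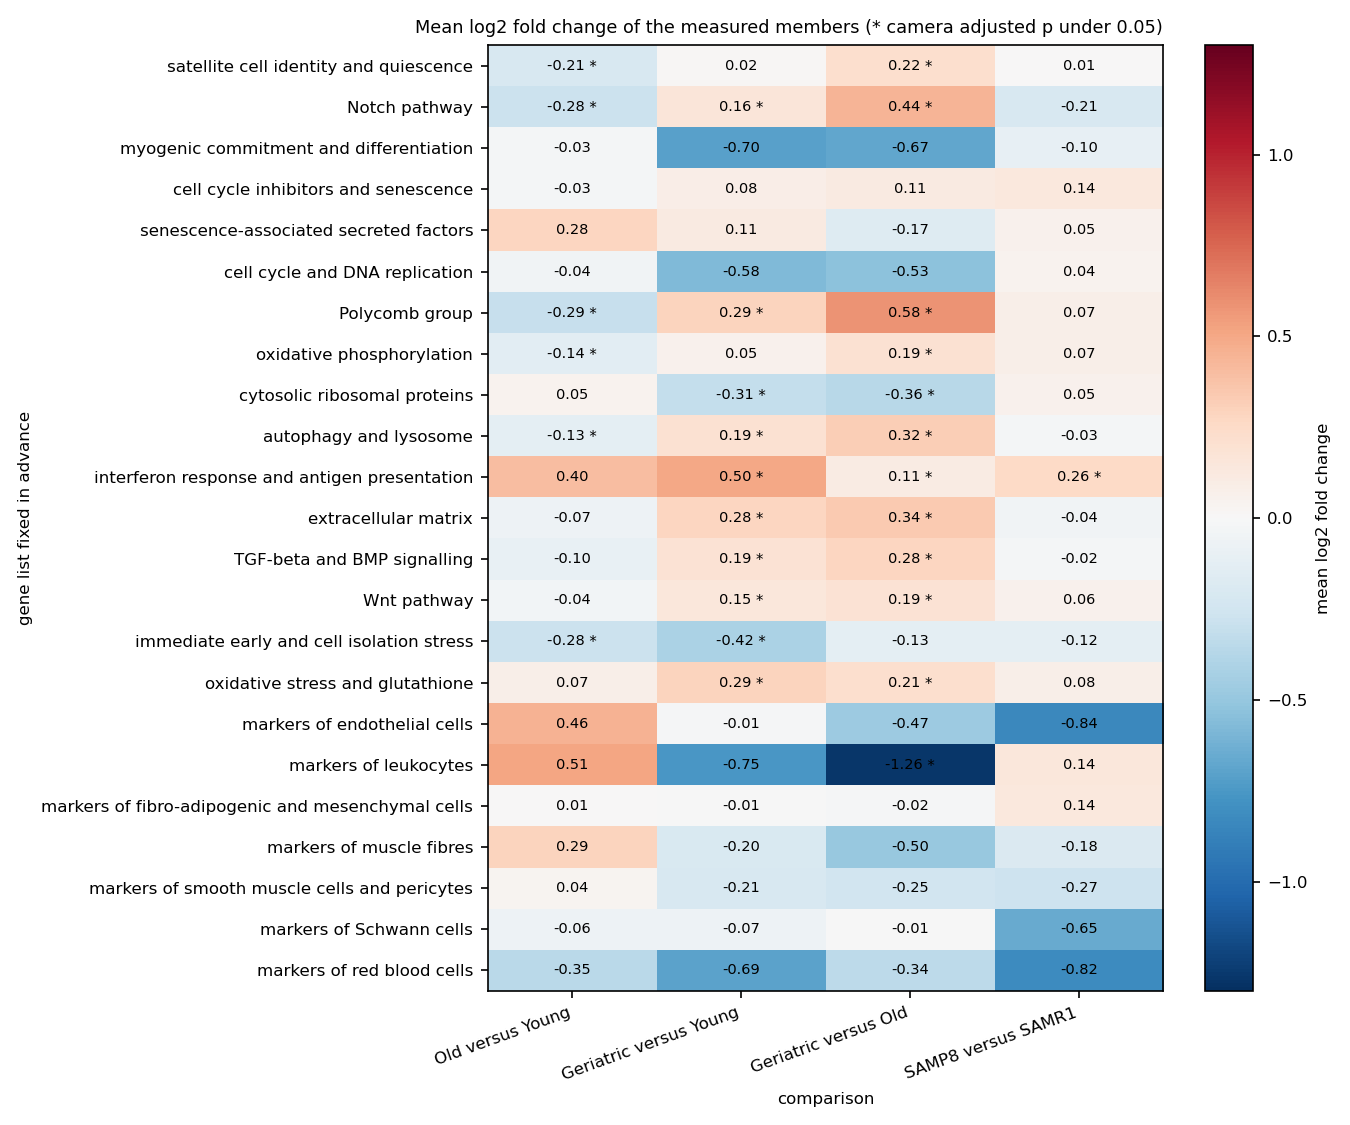
Mean log2 fold change of the measured genes of 23 lists (vertical) in 4 comparisons (horizontal), with an asterisk where camera's adjusted p passed 0.05. Polycomb genes had a mean of −0.29 in Old versus Young, 0.29 in Geriatric versus Young and 0.58 in Geriatric versus Old cells; ribosomal genes, at −0.31 and −0.36 in the Geriatric comparisons, flipped to 0.07 and 0.04 under quantile normalization.

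The changes of Old and of Geriatric cells against the same Young arrays were not alike across genes. Their log2 fold changes correlated with r = −0.157 (rho −0.161; genes are not independent replicates), where unchanged groups simulated against shared Young arrays gave r = 0.448. The covariance was −0.1142 against a simulated 0.1161, a difference of −0.2303. There were 53 genes higher in both (6.21 for independent lists), 8 lower in both (2.06) and 36 called in opposite directions. The 3 Young arrays cannot be split so that each part keeps 2, so part of the excess may come from the shared arrays. Within slide 2 the correlation was 0.096. It was −0.024 without Young 2, −0.083 without Young 1, −0.097 without Young 3, −0.086 without Old 1 and −0.054 without Geriatric 3.

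SAMP8 cells, from the senescence-prone strain, differed from SAMR1 cells in clusters of neighbouring immune genes and, near the threshold, in Cdkn2a, Cdkn2b and Myod1. Cdkn2b, the neighbour of Cdkn2a, rose by 1.70 ± 0.28 (log2, SE, n = 3 against 3, adjusted p = 0.0215), Cdkn2a by 1.17 ± 0.22 (adjusted p = 0.0457) and Myod1, the regulator of myogenic activation, by 0.90 ± 0.17 (adjusted p = 0.0429). Leaving out 1 array ended the calls of Cdkn2b, Cdkn2a and Myod1 in 4, 13 and 14 of 14 cases. Mean levels of Cdkn2b were −3.026 in SAMR1 and −1.324 in SAMP8, against −1.759, −1.733 and −2.613 in Young, Old and Geriatric cells. Those of Myod1 were 1.445 and 2.348, against 2.4, 2.357 and 2.043. For these 2 genes SAMR1 had the lowest level of the 5 groups, so the difference need not be a rise in SAMP8 cells. Cdkn2a had its highest level, −1.854, in SAMP8 cells. H2-D1, a class I antigen-presenting molecule, fell by 6.64 ± 0.38 (adjusted p = 6.78e-06), H2-Q8 by 5.39 ± 0.59 (adjusted p = 0.00134) and H2-Q7 by 1.58 ± 0.22 (adjusted p = 0.0087). In all, 148 genes differed (73 higher, 75 lower), of which 69 had symbols (28 higher, 41 lower) and 2 were chemosensory receptors, both higher. The share of higher calls was 49.3%, and 59.7% after normexp correction.

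Among the rises were Mrap2, a partner of melanocortin receptors (5.46 ± 0.84, adjusted p = 0.0154), Nkx1-2, a homeobox gene (4.47 ± 0.31, adjusted p = 2.73e-05), and Izumo3, of the sperm (at least 3.55-fold, adjusted p = 0.0456). Others were the taste receptor Tas1r1 (2.83 ± 0.41, adjusted p = 0.012), Zfp429 (2.53 ± 0.34, adjusted p = 0.00718), Trim12a (2.45 ± 0.41, adjusted p = 0.0237) and Nanogpd (2.43 ± 0.24, adjusted p = 0.00054). Nkx1-2 rested on 1 of 2 probes: the other changed by −0.14, and the mean of both by 2.17 (adjusted p = 0.0101). The falls included Arhgef37 (at least 49.2-fold lower, adjusted p = 0.000628), Nuf2 of the kinetochore (at least 21.5-fold, adjusted p = 0.00765), Klra8, a receptor of natural killer cells (at least 19.3-fold, adjusted p = 0.000249), and Emb (at least 16.5-fold, adjusted p = 0.00134). Amph (−5.72 ± 1.06, adjusted p = 0.0456) and Klra9 (−4.75 ± 0.72, adjusted p = 0.0143) were measured on 1 of 3 SAMP8 arrays each. The sizes of these falls therefore rest largely on values not well above background. The H2 and Klra genes are close copies of each other, so the values of single members are uncertain. Other kept probes of Klra8 changed by −6.451 and −0.015.

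Interferon response and antigen presentation was the 1 list that passed (higher, mean shift 0.26, camera adjusted p = 0.0164, adjusted p = 0.994 with an estimated correlation, 0.0109 against genes with symbols). Of its 41 genes 0 rose and 2 fell, H2-D1 and H2-Q7, and adjusted over the list alone 5 rose and 2 fell. Usp18 (1.45, adjusted p = 0.0523) and Cxcl10 (1.72, adjusted p = 0.198) did not pass over all genes. The shift was 0.27 with slide as a block (adjusted p = 0.0603), 0.56 within slide 1 and 0.20 within slide 2. The list was not called without SAMP8 2 (adjusted p = 0.0982) or SAMR1 2 (adjusted p = 0.0586).

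Cell cycle inhibitors as a list had an adjusted p of 0.292 (2 of 33 rose, Cdkn2a and Cdkn2b, also adjusted over the list alone), myogenic genes 0.977 (Myod1 rose), and the secretory phenotype 0.332 (0 of 42). Satellite cell identity had 0.938, the Notch pathway 0.598, Polycomb 0.501, oxidative phosphorylation 0.292, and ribosomal proteins 0.332. The values were for autophagy 0.988, extracellular matrix 0.949, TGF-beta 0.988, Wnt 0.694, immediate early genes 0.332, oxidative stress 0.332 and cell cycle and DNA replication 0.762. Median, mean and test differed in sign for 4 of them, the myogenic, autophagy, matrix and TGF-beta lists. Leukocyte markers had an adjusted p of 0.364, with Fcer1g, an Fc receptor subunit, up by 2.17 ± 0.37 (adjusted p = 0.0291). Mesenchymal markers had 0.332, muscle fibre 0.694, smooth muscle 0.292, Schwann 0.292 and red cell markers 0.332. Endothelial markers had a mean shift of −0.84 (adjusted p = 0.0772). Their mean level was −0.99 on SAMP8 3 and 1.91 and 2.03 on the other SAMP8 arrays, between 1.12 and 2.25 on the SAMR1 arrays, and between −3.62 and −0.61 on the Young, Old and Geriatric arrays. On SAMP8 3 red cell markers were also low (−2.36, against −0.197 and 1.43). Cdkn1a (0.74, adjusted p = 0.812), Pax7 (0.07, adjusted p = 0.985) and Myf5 (−0.16, adjusted p = 0.981) did not pass.

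Many calls lay close together on the chromosomes (mm9 coordinates of the probes). On chromosome 4 between 41604532 and 42803156, 15 calls were all higher, Cntfr and Ccl19 among them. On chromosome 17 between 6280617 and 6831039, 13 calls were lower, including Tmem181a, Dynlt1e and Dynlt1c, and between 35333097 and 35580315 there were 6 (1 higher, 5 lower), with Ltb, H2-D1, H2-Q8 and H2-Q7. Chromosome 6 held 3 lower calls between 129963349 and 130139716, Klra6, Klra8 and Klra9, and chromosome 4 between 88920405 and 89109487 held Cdkn2a and Cdkn2b and 1 lower call. Genes named here by place alone (Cntfr, Ccl19, Tmem181a, Dynlt1e, Dynlt1c, Ltb and Klra6) were chosen after their values were seen.

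**Figure D4:**
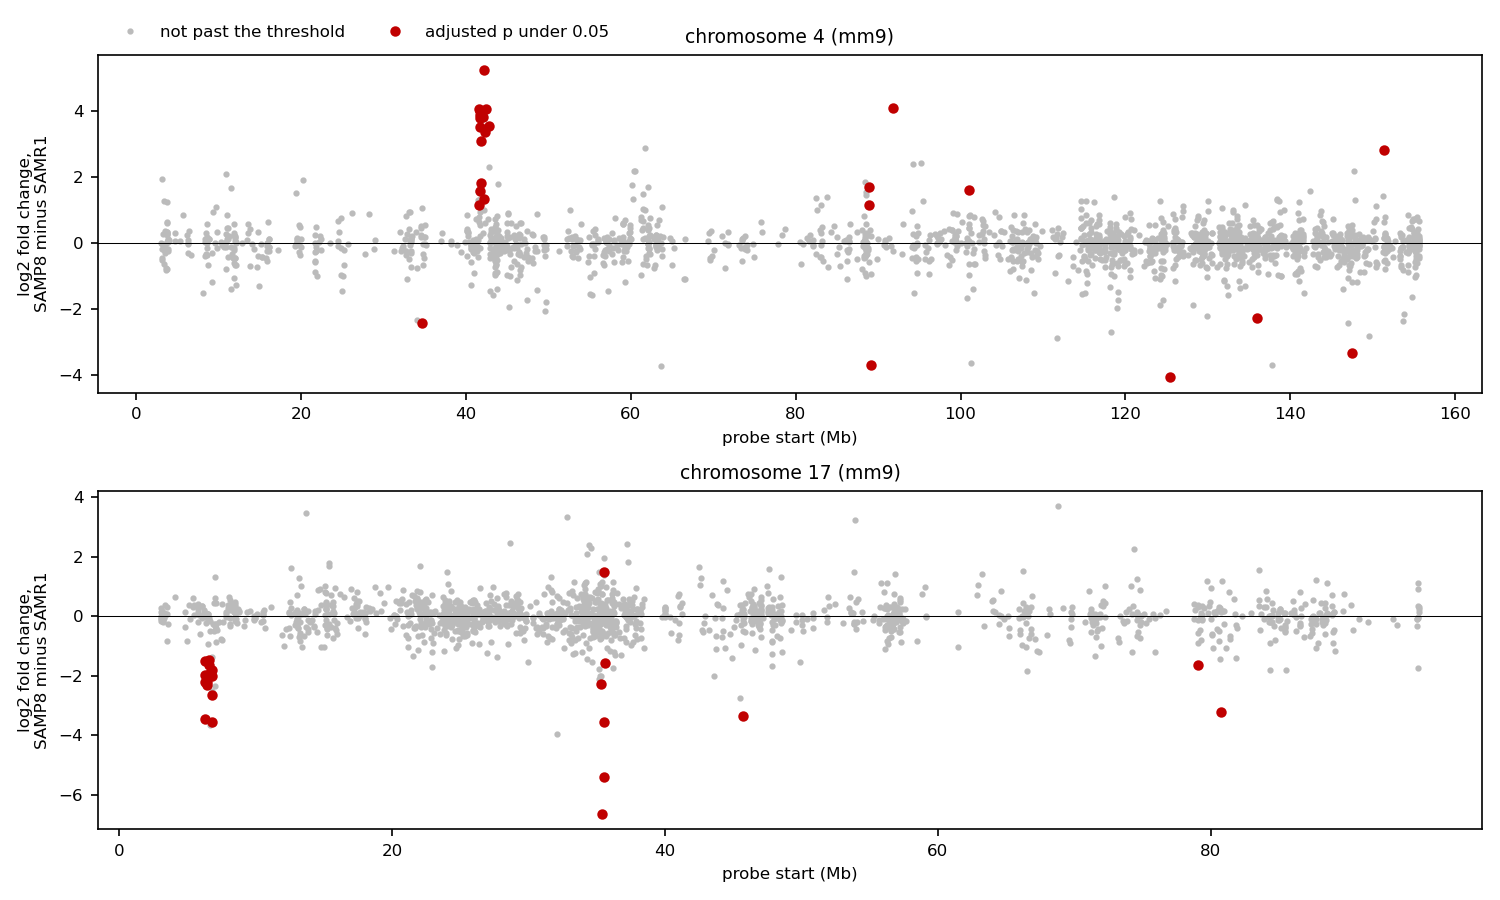
Log2 fold change in SAMP8 against SAMR1 cells (vertical) by probe position in Mb (horizontal, mm9) on chromosomes 4 and 17, with genes of adjusted p under 0.05 in red. The 15 calls near 42 Mb of chromosome 4 all lay above 0, and the 13 near 6 Mb of chromosome 17 below 0.

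With slide as a block 187 genes differed between SAMP8 and SAMR1 cells. Slide 1 holds 1 SAMP8 array and slide 2 holds 1 SAMR1 array, so here too fits within a slide (2 and 3 residual degrees of freedom) say little. In them limma called 0 genes on slide 1 (4388 at an unadjusted p under 0.05, lowest adjusted p = 0.167) and 0 on slide 2 (1619, lowest adjusted p = 0.106), and the 21 passing genes named in this text kept their direction in both. The count was 56 without SAMR1 2, 73 without SAMR1 1, 86 without SAMR1 3 and 250 without SAMP8 3. The calls of Cdkn2a, Cdkn2b and Myod1 lay near the threshold: leaving out 1 array lost them in 13, 4 and 14 of 14 cases, and over all settings they were lost in 23, 10 and 20 of 29. Without SAMR1 2 their adjusted p was 0.192, 0.112 and 0.112. That of Cdkn2b was also 0.11 without SAMR1 1, 0.0837 without SAMP8 1 and 0.0663 without SAMP8 2. Over all settings the adjusted p of the 3 genes ranged from 0.0213 to 0.638, 0.0101 to 0.607 and 0.00772 to 0.984.

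The Geriatric versus Young change differed from the SAMP8 versus SAMR1 change for 568 genes (177 higher, 391 lower, of them 123 and 70 with symbols and 0 and 68 chemosensory receptors). This test bears on whether the prone strain's cells changed as geriatric cells did. Only the Geriatric versus Young change also crosses the division in Ddx3y, Uty and Kdm5d detection, so a difference need not come from age. Cdkn2b moved apart (difference −2.56 ± 0.42, SE, adjusted p = 0.0113), as did Myod1 (−1.26 ± 0.25, adjusted p = 0.028). Both had their lowest mean level in SAMR1 cells (−3.026 and 1.445), which enters these differences. No difference was called for Cdkn2a (−0.17, adjusted p = 0.825), Cdkn1a (−1.95, adjusted p = 0.24) or Pax7 (−0.19, adjusted p = 0.787). Serpine2 (3.05, adjusted p = 0.00141), Perp (2.67, adjusted p = 0.012) and Nid1 (2.19, adjusted p = 0.017) were higher in the Geriatric change. Their mean levels were −1.873, −2.416 and 0.241 in Young and 1.054, 0.213 and 2.475 in Geriatric cells. They were 0.407, 0.1 and 2.644 in SAMR1 and 0.281, 0.054 and 2.689 in SAMP8 cells. For these genes both strains thus stood nearer to Geriatric than to Young cells. Across genes the changes correlated with r = −0.025 (rho 0.015), with 8 genes higher in both (1.15 for independent lists), 0 lower in both (1.96; 2738 and 7205 genes had an unadjusted p under 0.05 in SAMP8 versus SAMR1 and Geriatric versus Young) and 6 in opposite directions. The correlation of Old versus Young with SAMP8 versus SAMR1 was 0.076, with 3 genes higher in both, 0 lower in both (5551 at an unadjusted p under 0.05 in Old versus Young) and 2 opposite. The share of higher calls among the 568 was 31.2%, and 47.6% with the authors' values. With slide as a block the count was 590, and within slide 2, with 1 Young and 1 SAMR1 array, limma called 0 (2439 at an unadjusted p under 0.05, lowest adjusted p = 0.0513). It was 269 without Geriatric 3, 354 without Geriatric 1, 325 without Young 3, 322 without SAMR1 1, 317 without SAMR1 2 and 350 without SAMR1 3.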

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

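All tests of explanations in this part, except that of the 75th percentile normalization and the counts over other splits of the arrays, were chosen after the results were seen. Intervals in this part are over genes or probes, which are not independent, and do not measure the spread between arrays. The Geriatric versus Young change differed from the SAMP8 versus SAMR1 change at 568 genes by limma's test of the difference. The values below are the first change minus the second on the log2 scale, as fitted differences and not folds where a gene was near background. Sex-linked genes included Xist at −15.55, Ddx3y at 7.78, Uty at 6.15 and Kdm5d at 6.05. Vomeronasal receptors included Vmn1r101 at −9.88, Vmn1r121 at −9.58 and Vmn1r104 at −9.38. Secreted, matrix and signalling genes included Spock3 (4.72), Serpina3n (3.81), Il15 (3.81), Sfrp2 (4.42), Serpine2 (3.05), Timp3 (2.93), Nid1 (2.19), Dkk2 (−3.5), Pdgfrb (2.24) and Dpt (1.85). Among cell cycle and lineage genes were Perp (2.67), Cdkn2b (−2.56), Mki67 (−2.23), Myod1 (−1.26) and Nr4a2 (−1.77). The glutathione transferases Gstt3 and Gsta4 had differences of 1.68 and 1.95, the epithelial factor Grhl1 5.36 and the channel subunit Abcc9 −4.8. Genes led by the strain comparison were H2-D1 (6.65), H2-Q8 (6.7), H2-Q7 (1.82), Klra8 (4.23), Emb (4.63), Arhgef37 (5.37), Amph (7.72), Nuf2 (5.11), Nkx1-2 (−4.98), Mrap2 (−6.55), Nanogpd (−3.12), Zfp429 (−2.63), Tas1r1 (−2.97) and Trim12a (−2.83).

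Geriatric arrays differed from Young arrays at 1377 genes and Old arrays at 472, and they also differed in the sex-linked transcripts. Against an exchange of arrays between the Geriatric group and the Young or Old group, 0 of these 8 arrays showed the Xist and Y-linked state of another group; over all 14 arrays, the count first made, 1 SAMP8 array was unclear, and the restriction to 8 was made after that. Of X and Y genes 6.25% were called against 4.07% of autosomal genes, a ratio of 1.54 (one-sided exact p = 0.000166). By Xist and the Y-linked genes Young samples read as female and Geriatric ones as male, and this sex difference is a candidate explanation for that excess. For the autosomal calls it cannot be told apart from age, since SAMR1 arrays, which share the Geriatric state, differed from Old arrays in the same direction at 89.3% of 1262 calls, by 0.781 of the Geriatric change (95% interval 0.736 to 0.868), but differ from them in strain, age and markers of other cells too: endothelial markers had levels of 1.12 to 2.25 on SAMR1 and −2.35 to −0.61 on Old arrays, and red cell markers 0.075 to 0.785 and −2.54 to −1.94. The share was 0.507 over the 488 higher calls (95% interval 0.444 to 0.535) and 1.13 over the 774 lower ones (1.06 to 1.2), 136 of them receptors. SAMR1 arrays thus shared less of the higher calls, without a test of this over arrays. Age itself stays open and untested, and without X and Y genes 1281 genes were called.

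Chemosensory receptor genes, which serve smell and taste, had a median change of 0.85 in Old and −1.04 in Geriatric against Young cells and −1.99 between Geriatric and Old cells (0.74, −0.74 and −1.54 with genes below background at their bound). Against the 75th percentile normalization as the source, the last was −1.42 under quantile normalization. Against a shift of all dim probes, genes with symbols matched on their Young level shifted by 0.105 of it (95% interval 0.0715 to 0.148), and against array brightness the SAMP8 and SAMR1 arrays differed by 0.09 ± 0.19 in receptor median where brightness would give 1.17. The receptor median lay between −4.30 and −2.60 on Young and Old arrays and between −5.92 and −4.95 on Geriatric, SAMR1 and SAMP8 arrays, so age, strain and the sex-linked state stay open, and no biological explanation was tested. Intergenic probes moved the same way by less (median −0.44 between Geriatric and Old cells over 4488). Carried-over genomic DNA and differences in amplification, for which no separate test was run, therefore stay open, and the receptor values need not be receptor transcripts. With each array's receptor median as a covariate, a setting chosen after seeing the data, 22, 60 and 5 genes were called for Old versus Young, Geriatric versus Young and Geriatric versus Old, a covariate that itself differs between the groups.

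SAMP8 versus SAMR1 calls lay close together: 56 of 144 with a position had another within 1 Mb, where 100 random draws of as many genes gave 10 to 40 (median 24.5). Strain variants or copy number at a few loci are a candidate explanation, and Old versus Young calls, where no strain differs, had 220 of 465 against 170 to 243 in random draws. Sequence differences under single probes stay open, since 52.7% of 93 other probes of the called genes (95% interval 42.1 to 63.1) moved in the called direction by at least 0.5 of the called change. Cdkn2a and Cdkn2b lie in such a cluster, so a local difference between the strains stays open for them, as does a change of regulation.

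For Old versus Young and for SAMP8 versus SAMR1, 3 arrays against 3 make 10 splits, too few for a share under 0.05. The real split gave 472 and 148 genes and was 1 of 10 with as many in each case, and the highest other split gave 12 and 2.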

How the results depend on the processing

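Settings without X and Y genes, with gene symbols only and with the receptor median as a covariate were chosen after seeing the data. Over all settings 155 results of named genes that passed kept their direction in all of 4342 values and stayed past the threshold in 82.6% of them, and 17 did so in every setting. Cdkn2a and Myod1 in SAMP8 versus SAMR1 lost the call in 23 and 20 of 29 settings, and Foxo3, Maml2 and Pcgf6 in Old versus Young in 21, 21 and 20 of 29. Cdkn2a, Acvr2a and Nkg7 (Geriatric versus Young) and Amph and Izumo3 (SAMP8 versus SAMR1) lost it in 18 of 28 settings each. As the mean of all kept probes, 5 of the 155 changed by less than 0.5 of their reported change: Foxo3 in Old versus Young (0.02, from 0.91) and in Geriatric versus Old (−0.31, from −1.29), Rpl7a in Geriatric versus Old (−0.01, from −0.71), Ppargc1a in Old versus Young (1.0, from 2.0) and Nkx1-2 in SAMP8 versus SAMR1 (2.17, from 4.47). The 29 list calls stayed in 77.8% of 609 values, none in every setting (0 with an estimated correlation, 3 with fry and 10 against genes with symbols). Ribosomal genes turned under quantile normalization (adjusted p = 0.0832 for Geriatric versus Young and 0.521 for Geriatric versus Old). Signal over background, 4.61 to 6.66, limits dim genes, of which many have only a bound. Within a slide all comparisons but Geriatric versus Old have a group of 1 array, so their counts there say little about stability. Where leaving out an array left 1 Geriatric array, it was assumed to vary like the other groups. Except where a setting tested fewer genes or used fewer arrays, the cause was not tested.

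For Old versus Young, the 472 genes became 1036 after normexp correction, 773 with the authors' values, 305 with probes above background on all arrays, 729 with slide as a block, 0 within slide 1 and 0 within slide 2 (4901 and 2723 at an unadjusted p under 0.05 in limma), 43 with the compared groups alone, 176 with gene symbols only and 22 with the covariate. Leaving out 1 array gave 85 (Old 1) to 793 (Old 3). The 1377 genes of Geriatric versus Young became 915 with probes above background on all arrays, 862 with slide as a block, 2 within slide 2, 416 with the compared groups alone, 2677 with array weights, 422 with symbols and 60 with the covariate, and 416 (without Geriatric 3) to 1536 with 1 array left out. For Geriatric versus Old, 6557 became 1554 within slide 2, 2998 with the compared groups alone, 2291 with symbols and 5 with the covariate, and 1995 (without Geriatric 3) to 7309 with 1 array left out. The 148 of SAMP8 versus SAMR1 became 263 after normexp correction, 228 with the authors' values, 0 within slide 1 and 0 within slide 2 (4388 and 1619 at an unadjusted p under 0.05 in limma), 47 with the compared groups alone, 300 with array weights and 68 with symbols, and 56 (without SAMR1 2) to 250 (without SAMP8 3) with 1 array left out. The 568 differences between the Geriatric and SAMP8 changes became 883 after normexp correction, 328 with probes above background on all arrays, 0 within slide 2 (2439 at an unadjusted p under 0.05 in limma), 1054 with array weights, 153 with symbols and 59 with the covariate, and 269 (without Geriatric 3) to 772 with 1 array left out. Without X and Y genes the 5 counts were 451, 1281, 6291, 146 and 526.

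The correlation of Old with Geriatric changes, −0.157, was 0.096 within slide 2 and −0.041 with symbols only, and −0.223 (without Geriatric 1) to −0.024 (without Young 2) with 1 array left out. That of Geriatric with SAMP8 changes, −0.025, was 0.024 with the authors' values, 0.046 with probes above background on all arrays, 0.004 with slide as a block, 0.014 with array weights and 0.039 with symbols, and −0.094 (without SAMP8 3) to 0.053 (without SAMP8 2) with 1 array left out.

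Of the lists for Old versus Young, 6 passed, against 2 under quantile normalization (Polycomb and immediate early genes, adjusted p = 0.000371 and 0.0054), 0 with an estimated correlation, 1 with fry (the secretory phenotype, higher, adjusted p = 0.0435, which is none of the 6, whose fry adjusted p ran from 0.0902 to 0.824), and 2 (without Old 1) to 11 (without Old 3) with 1 array left out; without Old 2 it was 3 and without Young 3 it was 10. For Geriatric versus Young 10 passed, against 4 with slide as a block, 0 with an estimated correlation, 0 with fry and 3 (without Geriatric 3) to 15. For Geriatric versus Old 12 passed, against 0 with an estimated correlation, 3 with fry, 3 with symbols and 6 (without Geriatric 3) to 15. For SAMP8 versus SAMR1 1 passed, against 0 with slide as a block, 0 with an estimated correlation, 0 with fry, and 0 (without SAMR1 2) to 3 (without SAMP8 2).

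Deviations of same-numbered arrays correlated between −0.255 and −0.213 (Old and Young) and between −0.166 and 0.033 (SAMP8 and SAMR1). They correlated between −0.13 and −0.064 (Geriatric and Young) and between 0.114 and 0.156 (Geriatric and Old, 2 pairs). Arrays of other numbers gave, in the same order, 0.049 to 0.197, −0.112 to 0.131, −0.06 to 0.132 and −0.159 to 0.055. Same-numbered arrays shared a slide only for Geriatric and Old, so this check cannot tell pairing by number from slide. With a replicate block 237 genes were called for Old versus Young, 869 for Geriatric versus Young and 349 for the difference between the Geriatric and SAMP8 changes.

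Single genes that did not pass turned in places. Cdkn2b in Old versus Young was −0.184 under quantile normalization, −0.016 with median centring, −0.092 with the authors' values, −0.03 with array weights and −0.106 as the mean of its probes, and −0.126 to 0.246 with 1 array left out. Myod1 in Old versus Young was 0.035 under quantile normalization, 0.021 with the percentile of probes detected on all arrays, 0.044 with the authors' values and 0.019 within slide 1, and −0.107 to 0.025 with 1 array left out. Pax7 was 0.108 (quantile) and 0.169 (authors' values) in Geriatric versus Young, and −0.283 to 0.054 with 1 array left out, and −0.03 (slide as a block) and −0.227 (slide 1) in SAMP8 versus SAMR1, and −0.046 to 0.211 with 1 array left out. Within slide 2, Cdkn1a was −0.129 and Myf5 0.292 in SAMP8 versus SAMR1, and Cdkn2a in Geriatric versus Old was −0.007 after normexp correction.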

Other observations

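Genes in this part were chosen after their values were seen, and no explanation was tested for them. The chemokine Ccl11, the secreted inhibitor Serpina3n and the metalloprotease inhibitor Timp3 were higher in both Old and Geriatric cells than in Young cells. The mean level of Ccl11 was −4.80 in Young, −1.37 in Old and 0.61 in Geriatric cells, and its rise from Old to Geriatric passed too (1.99, adjusted p = 0.0329). Timp3 stood at −0.49, 1.02 and 2.05, with a further rise of 1.03 (adjusted p = 0.0141) between the older groups. In SAMR1 and SAMP8 cells Timp3 stood at 3.15 and 2.76, and Ccl11 at −1.81 and 0.23. The step from Old to Geriatric also crosses the division in sex-linked transcripts, so it cannot be assigned to age alone. Serpina3n rose by 2.98 in Old (adjusted p = 0.0173) and 2.85 in Geriatric cells (adjusted p = 0.0146). Ppargc1a, a coactivator of mitochondrial biogenesis, rose by 2.00 (adjusted p = 0.00203, but 0.225 as the mean of its probes) and 2.32 (adjusted p = 0.000589), and the lipid carrier Apoe by 0.83 (adjusted p = 0.0344) and 0.77 (adjusted p = 0.0382). The calls of Apoe were lost in 14 of 29 and 13 of 28 settings, among them 9 of the 14 that leave out 1 array each. The chemokine Ccl19 rose by 1.21 in Old (adjusted p = 0.0183), 0.98 in Geriatric (adjusted p = 0.0345) and 1.35 in SAMP8 cells (adjusted p = 0.0138), where it lies in the cluster of higher calls on chromosome 4. In SAMP8 against SAMR1 cells the other kept probes of Ccl19 changed by 1.494 and −0.164, so its probes disagree. Rgs2, a regulator of G protein signalling, fell by 0.96 in both (adjusted p = 0.0334 and 0.0257).

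These belong to 61 genes called in the same direction at both ages. Of the 53 higher ones, 37 had gene symbols and 3 lay on X or Y, their median change was 1.9 in Old and 2.31 in Geriatric cells, 43 had the larger change in Geriatric cells, and 10 of these differences passed the test between Geriatric and Old. In SAMP8 against SAMR1 cells 34 of the 53 moved in the same direction and 2 were called. The 8 lower genes, 7 with symbols, had medians of −2.36 and −2.58. Old and Geriatric cells were compared with the same Young arrays, so part of this sharing can arise from those arrays. Only the Geriatric samples also differed from Young ones in sex-linked transcripts, so their larger changes cannot be assigned to age alone.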
